A study of Homo sapiens with 28 samples.

How the data were processed

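The series holds 28 arrays of human bladder epithelial cells: 4 APF and 4 mock arrays of the run experiment, 2 APF and 2 mock arrays for each of 2 cell lines, 6 IC and 6 normal arrays. Groups were taken from the labels, and so were the membranes (A or B) of the 16 APF and mock arrays. For the first pair of the run experiment the number is only the order of deposit. For 1 mock array of line 2 the title and the description name different preparations, and the title was followed.

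The values come from the table of 4132 probes and 28 columns deposited by the authors. How the authors made it (scanner, background method, software) is not given in the sources used here. From the values themselves, each deposited column is on another scale than log2: the cubes of its values sum to 1 in each of the 28 arrays (to 4 decimals), and between 9.87% and 35.1% of the values are negative. The deposited values were therefore read as signed cube roots of each probe's share of the array's summed net signal, with negative values for spots below background. This reading, which no label states, underlies every level given in ppm (the cube times 1000000). Dividing by the array total makes each level relative: when a few bright probes take a smaller share of the signal, others take a larger one. The 100 brightest probes of an array held between 23.3% and 59.5% of its net signal, and the median probe read between 6.39 and 53.2 ppm.

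The background limit of an array was set at the size of its negative values, at their 0.95 quantile, on the assumption that noise around 0 is symmetric. A fold is the ratio of 2 group means in ppm. Where no array of the dimmer group was above its limit, each of its arrays was set to the higher of its limit and its own value and the fold is given as "at least"; no fold is given where both groups were below the limit or the ratio was under 1. For CDKN1B in line 2, where 1 of 2 mock arrays was above its limit, the other was raised to its limit in the same way. Correlations between arrays of 1 group ranged from 0.426 to 0.951, and 0 arrays had identical values.

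Of the probes, 3369 have 1 gene symbol in the platform's annotation, which can be old, 103 have several and 660 have none listed there. Of the single-gene probes, 3364 matched a current gene by its identifier in the RefSeq table of assembly GRCh38.p14, which was used for names only, and 5 kept the platform's symbol. The 6 probes of XIST and of genes on the Y chromosome were removed before any test, leaving 4126. Probes were tested singly, and 73 genes had more than 1 probe.

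The tests had been fixed before the data were examined for log2 values. Because negative values have no log, limma (version 3.58.1, R 4.3.3; lmFit and eBayes, two-sided, Benjamini-Hochberg over all probes, threshold 0.05) was run on the deposited scale, without further normalization, and differences and standard errors are on that scale. The run experiment and the cell line experiment were fitted separately with the membrane as a covariate, the latter with a mean per group and the APF difference averaged over the 2 lines. With the membranes as they were assigned, that average takes nothing from the second APF and mock arrays of line 1, and the difference between the lines takes nothing from the first, which was checked on the estimates. Both together were fitted with a mean for the run experiment and each line and the membrane within each experiment. IC was compared with normal with no covariate. Gene lists with at least 5 measured genes (28 of 29; the remaining list had 4) were tested with limma's camera at a preset correlation of 0.01, with 1 probe per gene, that of the highest mean, and again with an estimated correlation and with fry. Fold-change correlations were tested by regrouping the arrays, with 100 regroupings, the real one included.

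Named genes were chosen by a rule fixed before the data were examined. In each main comparison these were the 8 single-gene probes with the largest positive and the 8 with the largest negative difference past the threshold or, where fewer than 12 passed, those and the next by p up to 12. To these were added the 3 members of lowest p, in the list's direction, of each list past the threshold, and the 3 of lowest p of the panel of genes discussed for APF. For the difference between lines the 3 of lowest p were taken.

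The fits were tested on simulated data with the real probe means and spreads over 4126 probes, of which 200 were changed. A difference of 0.08 was called in 87% of 100 probes in the run experiment, 71% in the cell line experiment, 99% in both together and 92% in IC against normal. A difference of 0.04 was called in 44%, 29%, 79% and 34%, respectively. A list shifted by 0.02 was called in each of the 4 comparisons, with 0 other lists. These simulations have independent probes and arrays, which the real arrays need not have.

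Alternatives were median centring, quantile normalization, removal of the dimmest 0.25 of the probes, a trended and robust variance, array weights, all 28 arrays in 1 fit, no membrane term, the replicate number as a block, fits within a membrane or a line, and leaving out each array. Chosen after seeing the data were a log2 scale with levels under 10 ppm raised to 10, a restriction to probes above background on at least 0.5 of the arrays, and the division of the IC and normal arrays by number.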

Results

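Bladder epithelial cells were profiled on 28 arrays of 4132 probes each, in 3 sets of comparisons. The first set, called the run experiment here, held 4 arrays of normal bladder cells treated with antiproliferative factor (APF) and 4 of cells given mock APF. APF is a small sialoglycopeptide, made by bladder epithelial cells of people with interstitial cystitis (IC), that slows the growth of normal bladder epithelial cells. The second set, the cell line experiment, held 2 APF and 2 mock arrays for each of 2 normal bladder cell lines. By their titles, the 2 arrays of a group were given differently numbered APF or mock preparations. Their SD therefore includes any difference between preparations. The third set held cells from 6 people with IC, a chronic painful bladder disease, and from 6 normal controls. The deposited values were read from their properties, since no label states their scale, as cube roots of each probe's share of the net signal on its array, and levels are given below as that share in parts per 1000000 (ppm). The precision was limited by the number of arrays. The background limit of an array lay between 43.8 and 149 ppm, and between 17.8% and 46.0% of the probes on an array were above it. The labels do not say whether the arrays of a group came from separate cultures, so the p-values of the APF comparisons measure the spread between these arrays, whatever its source.

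The run experiment asked which transcripts differ between APF and mock-treated normal bladder cells. None of the 4126 probes tested passed the threshold with limma. An unadjusted p under 0.05 was found for 83 probes, fewer than the share of 0.05 that chance alone gives on average. Among the 12 single-gene probes with the lowest p, beta-actin (ACTB), a cytoskeletal protein, was the one with every array above background. It read 3160 ± 844 ppm with APF and 6071 ± 1221 ppm with mock (SD, n = 4 each), a value 1.92-fold lower with APF, and its adjusted p was 1.00. A further ACTB probe differed by -0.0184 ± 0.0159 (SE) on the deposited scale. Vimentin (VIM), the intermediate filament protein of mesenchymal cells, read 3549 ± 2330 ppm with APF and 6212 ± 3296 ppm with mock, and the gelatinase MMP2 read 1909 ± 1121 and 3244 ± 1530 ppm (SD, n = 4 each). VIM, MMP2 and the tight junction protein TJP1 were the panel genes (genes discussed for APF before the data were examined) with the lowest p in this comparison, and none passed (adjusted p = 1.00 for each). TJP1 was below the background limit on all 8 arrays.

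The other probes of low p in the run experiment lay at or near background. LONP2, JAK1, GMPR, MTM1, EFNA1, MEIS2, NRP1 and LTBP4 were above the limit on 0 of the 8 arrays, so their differences have no interpretable level. MYH10, a nonmuscle myosin heavy chain, was above the limit on 2 of 4 mock arrays and 0 of 4 APF arrays, at least 1.18-fold lower with APF. EMP3 was above it on 2 of 4 mock arrays, RFC4 on 1 of 4, and neither on an APF array. Within membrane A alone and within membrane B alone (2 against 2 arrays each), the count of probes past the threshold was also 0, with 302 and 518 probes at an unadjusted p under 0.05.

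None of the 28 gene lists passed camera in the run experiment. The lowest p was that of the endothelial markers (14 genes measured, 10 with a positive and 4 with a negative difference, adjusted p = 0.0716). Their adjusted p was 0.956 with an estimated correlation. The member with the lowest p was the angiopoietin receptor TEK, with a difference of 0.0279 ± 0.00911 (SE) and an adjusted p of 1.00, below the background limit on all 8 arrays. Without the third mock array the endothelial markers passed, at an adjusted p of 0.0430, and of 0.922 with an estimated correlation. Of the 18 fibroblast and smooth muscle markers, 15 had a negative difference, and the list's adjusted p was 0.2495. Of these, ACTA2, smooth muscle actin, differed by -0.0321 ± 0.0107 and MYLK, the kinase of myosin light chain, by -0.0390 ± 0.0159 (SE). ACTA2, MYLK and TEK were chosen here after their values were seen. The matrix proteases and their inhibitors (28 genes, 23 with a negative difference) had an adjusted p of 0.845 with camera. With fry, which tests whether the genes of a list move one way on balance, that list had an adjusted p of 0.0236 (0.956 with camera at an estimated correlation) and a median difference of -0.00495, beside a median of -0.00247 over all probes. In each of the 28 lists, 0 members passed over all probes and 0 when adjusted over the list alone.

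In the cell line experiment 84 probes passed the threshold, 72 of them higher and 12 lower with APF than with mock, and 874 had an unadjusted p under 0.05. TSC2, which encodes tuberin, a brake on mTOR signalling, read 1574 ± 1700 ppm with APF and -1.34 ± 2.50 ppm with mock in line 1, at least 11.7-fold higher with APF. In line 2 it read 7183 ± 1441 and 2.69 ± 26.1 ppm, at least 55.5-fold higher (SD, n = 2 per group; adjusted p = 0.0291). CDKN1B, which encodes the inhibitor of cyclin-dependent kinases p27, rose from 187 ± 42.8 to 1300 ± 1182 ppm in line 1, 6.95-fold. In line 2 it rose from 121 ± 29.4 to 5704 ± 140 ppm, at least 42.3-fold with the mock array below its background limit (1 of 2) raised to that limit (SD, n = 2; adjusted p = 0.0225). BRME1, a meiotic recombination gene and 1 of the brightest probes of the arrays, fell 4.78-fold in each line, from 14134 ± 168 to 2959 ± 1574 ppm in line 1 and from 9863 ± 1453 to 2065 ± 186 ppm in line 2 (SD, n = 2; adjusted p = 0.0208).

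Of the other probes with the largest increases, the immunoglobulin superfamily gene IGDCC4 was at least 9.07-fold higher with APF in line 1 and at least 39.7-fold in line 2 (adjusted p = 0.00106). The deubiquitinase ZRANB1 was at least 6.03-fold and 24.6-fold higher in lines 1 and 2, and AP3S2, a subunit of a vesicle adaptor complex, at least 6.25-fold and 24.6-fold (adjusted p = 0.0187 and 0.0266). LLGL2, a cell polarity gene, was at least 2.71-fold and 8.97-fold higher, and PPP2R3A, a regulatory subunit of a protein phosphatase, at least 2.07-fold and 10.96-fold (adjusted p = 0.0266 and 0.0187). LLGL2 and PPP2R3A were above background on 1 of the 2 APF arrays of line 1. The chemokine CCL16 was at least 3.24-fold higher in line 2 and above background on 1 APF array in line 1 (adjusted p = 0.0311). These 6 genes were below the limit on all 4 mock arrays. In line 1, ZRANB1 averaged 812 ± 936 ppm with APF, AP3S2 841 ± 941 ppm and IGDCC4 1220 ± 1422 ppm (SD, n = 2), and the line 1 folds rest mostly on the first APF array. From the second APF array alone they were at least 1.12-fold for ZRANB1, 1.31-fold for AP3S2, 1.59-fold for IGDCC4 and 2.77-fold for TSC2, and 2.48-fold for CDKN1B. LLGL2, PPP2R3A and CCL16 were below the limit on that array. Further probes of IGDCC4 and ZRANB1 did not pass, with differences of 0.0307 ± 0.00731 and -0.00550 ± 0.00708 (SE).

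Among the probes lower with APF, the inositol phosphatase INPP5J fell 3.11-fold in line 1 and 2.18-fold in line 2, and the transcription factor CUX1 fell 3.69-fold and 3.04-fold (adjusted p = 0.0291 and 0.0306). From the second line 1 APF array alone these line 1 folds were 2.33 and 2.81, and that of BRME1 was 3.47. COX7C, a subunit of cytochrome c oxidase, fell 2.99-fold and 2.37-fold, and PDE6H, a phosphodiesterase subunit of cone photoreceptors, 3.77-fold and 2.70-fold (adjusted p = 0.0367 and 0.0271). From the second line 1 APF array alone the line 1 folds of COX7C and PDE6H were 2.34 and 2.51. CXCL10, AKTIP and MAPKAPK3 also passed but were below the background limit on all 8 arrays, so no fold is given. In 15 of these 16 probes both APF arrays of each line lay beyond both mock arrays of that line, and in MAPKAPK3 3 of the 4 APF arrays did, a separation largely fixed by selecting the probes on these same arrays. Among all 84 probes that passed, 26 were at or below the limit on all 8 arrays.

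**Figure D1:**
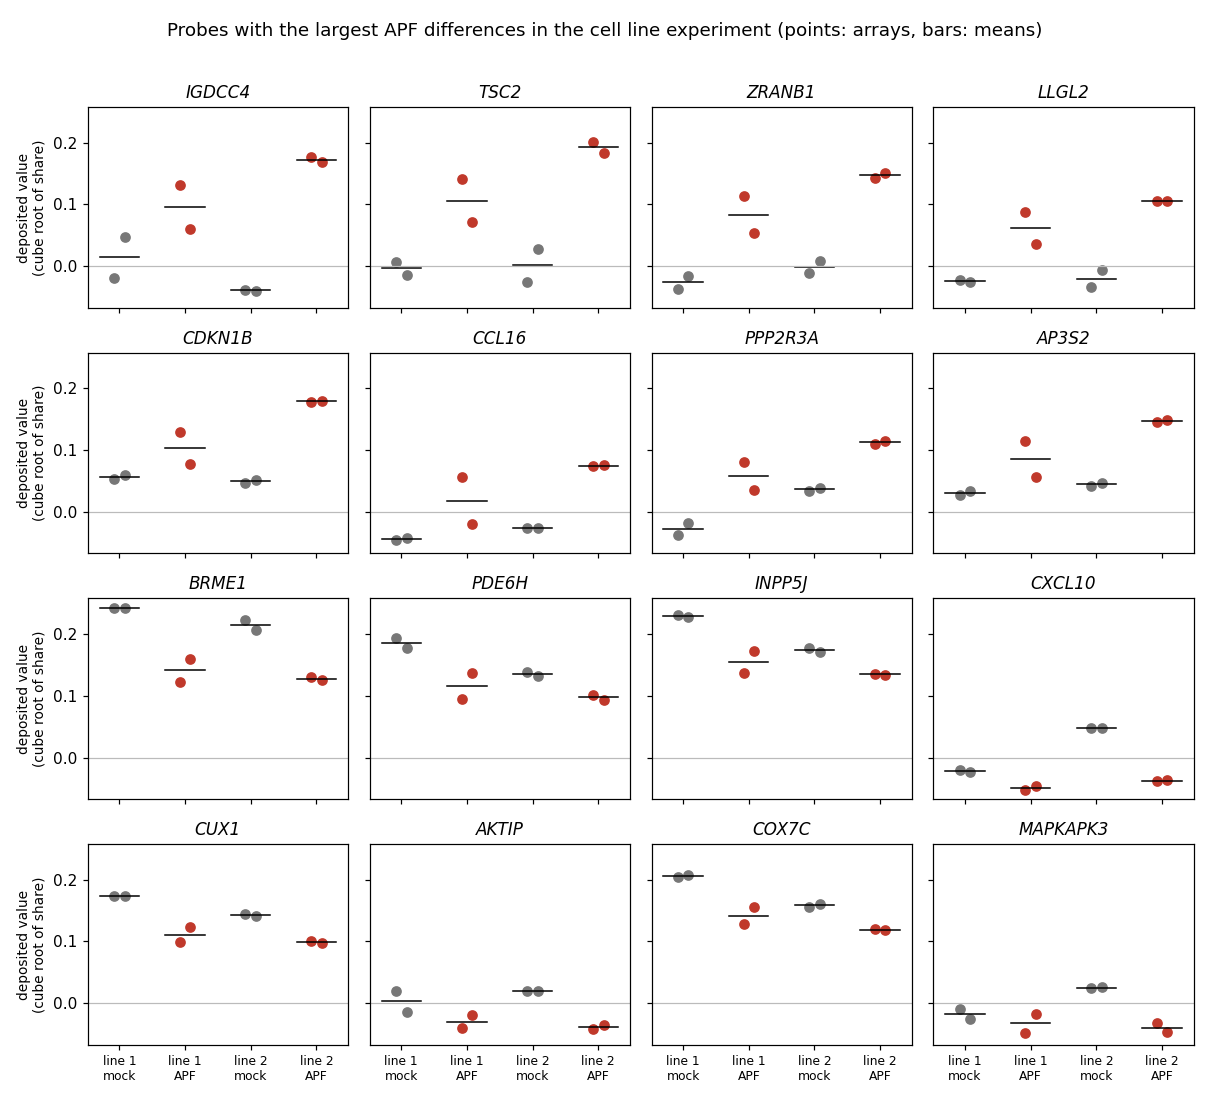
Deposited values (cube root of the share of net signal, y axis) of the 16 single-gene probes with the largest differences past the threshold, 8 higher and 8 lower with APF, by line and treatment (x axis). Points are arrays, 2 per group, bars are group means, and values below 0 are below background. TSC2, IGDCC4 and CDKN1B stand highest in the APF arrays of line 2, and the 2 APF arrays of line 1 lie apart from each other.

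No gene list passed camera in the cell line experiment, where the lowest adjusted p was 0.900 with the preset and 0.969 with an estimated correlation. Camera compares a list with all other genes, whose median difference was above 0 here, so lists such as the cell cycle genes (median 0.00363, mean 0.00311) had a positive median and mean and a downward test. Of the 49 cell cycle genes, 1 passed over all probes and 1 when adjusted over the list alone, in each case CDKN1B. The proliferation marker MKI67 differed by -0.0245 ± 0.00761 and CDK1, the mitotic kinase, by -0.0392 ± 0.00827 (SE), and neither passed (adjusted p = 0.141 and 0.0751). MKI67 was below the background limit on all 8 arrays and CDK1 above it on 1, so these differences have no interpretable level. Of 14 keratin and urothelial differentiation genes, 2 passed over all probes and 2 adjusted over the list alone. These were the suprabasal keratin KRT10, at 0.0793 ± 0.0133, and the cornified envelope gene SPRR1B, at 0.0453 ± 0.00749 (SE; adjusted p = 0.0484 and 0.0481), with KRT10 above the background limit on 0 and SPRR1B on 1 of the 8 arrays. Of 20 cell junction genes 1 passed, the afadin gene AFDN, at 0.0709 ± 0.0103 (SE; adjusted p = 0.0326) and below the limit on all 8 arrays, and 5 passed adjusted over the list alone, 4 higher and 1 lower. Of 31 proteasome and ubiquitin genes 3 passed, PSMD14 and CUL1 higher and PSMA1 lower, and 5 adjusted over the list alone. CUL1 was below the limit on all 8 arrays, PSMD14 above it on 3 of 4 APF and 0 of 4 mock arrays, and PSMA1 above it on all 8. Of 34 splicing genes, the small nuclear ribonucleoprotein genes SNRPC and SNRPE passed, both higher, over all probes and over the list alone, with SNRPC below the limit on all 8 arrays and SNRPE above it on 3 of 4 APF and 0 of 4 mock arrays. Of 35 cytokine and NF-kappaB genes, TNFAIP2 passed higher (above the limit on 4 of 4 APF and 0 of 4 mock arrays) and CXCL10 lower (below it on all 8), and 6 passed adjusted over the list alone, 3 in each direction. On the 4 mock arrays of the run experiment, AFDN, SPRR1B, TNFAIP2, PSMA1 and CDKN1B were above the limit on 4. There KRT10, PSMD14 and SNRPE were above it on 3, and CUL1, SNRPC and CXCL10 on 0. List members given here that are outside the fixed rule were chosen after their values were seen.

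Of the panel of genes discussed for APF, IGFBP3, CDH1 and IGF1 had the lowest p in the cell line experiment, and 0 of 21 passed over all probes, 2 adjusted over the list alone. CDH1, which encodes E-cadherin, read 572 ± 6.74 ppm with APF and 9.82 ± 4.09 ppm with mock in line 2, at least 4.42-fold higher (adjusted p = 0.0642, and 0.0479 without the membrane term). In line 1 it read 137 ± 166 and 6.94 ± 3.53 ppm (SD, n = 2), above background on 1 APF array. IGFBP3, an insulin-like growth factor binding protein, read 595 ± 41.5 and 131 ± 24.8 ppm in line 2, and 97.6 ± 119 and 8.61 ± 10.99 ppm in line 1 (adjusted p = 0.0625). IGF1 was below the limit on all 8 arrays. With fry, the interferon and antigen presentation genes (40 measured, 28 with a positive difference) had an adjusted p of 0.0309 and a median difference of 0.0126, beside a median of 0.00691 over all probes. With camera, which compares them with the other genes, their adjusted p was 0.900, and 0.969 with an estimated correlation. Of these genes 0 passed over all probes and 0 adjusted over the list alone.

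The cell line calls rest on few arrays. In line 2 treatment coincided with the membrane, and the fit took the membrane difference from line 1. In this layout the second APF and mock arrays of line 1 cancel out of the average difference, which equals the mean of the line 2 difference and the difference between the first APF and first mock arrays of line 1 (largest deviation 0 over all probes). In the called direction, the mean difference of the 84 probes was 0.0764 in line 2, 0.0707 in the first pair of line 1 and 0.0250 in the second pair. The sign was that of the call in 84, 83 and 72 of the 84 probes, respectively. The first and second pairs of line 1 also differ in the number of the preparation. A difference between these pairs thus cannot be told apart from one between preparations. Without the membrane term, which brings the second pair in, 143 probes passed, 65 of them among the 84, and 14 of the 16 probes plotted passed (AKTIP and MAPKAPK3 did not, adjusted p = 0.0508 and 0.0606). As contrasts of the same fit, line 1 alone gave 0 probes (513 at an unadjusted p under 0.05) and line 2 alone gave 20. Leaving out any 1 of the 4 line 2 arrays left 1 probe. Leaving out a line 1 array gave 278 (first APF), 1488 (first mock), 989 (second APF) and 989 probes (second mock), in fits whose spread comes from the line 2 arrays alone. With array weights 1 probe passed, and with all 28 arrays in a single fit 19 did. With the number of the APF or mock preparation as a block, 0 probes passed, with the membrane term (1480 at an unadjusted p under 0.05, limma) or without it (707). For IGDCC4 the difference was then 0.180 (adjusted p = 0.0671) and 0.146 (adjusted p = 0.0651), the same differences as without the block. The block left fewer than the 3 residual degrees of freedom of the main fit. The count of 0 therefore cannot tell a loss of precision from an effect of pairing. The share of net signal in the 100 brightest probes was 46.0 ± 1.08% with APF and 58.0 ± 2.12% with mock in line 2, and 37.4 ± 3.83% and 40.7 ± 1.36% in line 1 (SD, n = 2). With quantile normalization 78 probes passed, 75.6% of them higher against 85.7% with the deposited values.

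The APF difference itself was compared between the lines. IGDCC4 passed, with an APF difference larger in line 2 than in line 1 by 0.199 ± 0.0146 (SE; limma adjusted p = 0.0366). It read 5144 ± 427 ppm with APF in line 2 and 1220 ± 1422 ppm in line 1 (SD, n = 2). In the fit this difference equals the line 2 difference minus that of the second line 1 pair, 0.212 minus 0.0126 for IGDCC4, while the first pair differed by 0.149. The call was absent with median centring or quantile normalization, and without the membrane term, where the difference was 0.131 (adjusted p = 0.296). For a further IGDCC4 probe the difference between lines was 0.0153 ± 0.0146 (SE), and it did not pass. CUL1 and ISLR had the next lowest p (adjusted p = 0.251 and 0.315) and were below the limit on all 8 arrays. In all, 325 probes had an unadjusted p under 0.05 for this difference. Without the second mock array of line 1 509 probes passed, and without any 1 of the other 7 arrays 0 did.

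With the 16 arrays of both APF experiments together, limma called 0 probes, and 292 had an unadjusted p under 0.05. PDK3, a pyruvate dehydrogenase kinase, was above background on all 16 arrays. It read 794 ± 679 ppm with APF and 1168 ± 491 ppm with mock in the run experiment (SD, n = 4). In line 1 the values were 1192 ± 611 and 4046 ± 216 ppm, and in line 2 827 ± 146 and 1610 ± 97.3 ppm (SD, n = 2; adjusted p = 0.626). BRME1 read 3513 ± 2871 and 5105 ± 1866 ppm and CUX1 1462 ± 917 and 2302 ± 931 ppm in the run experiment (SD, n = 4), with adjusted p = 0.626 each over both experiments. TSC2 read 3314 ± 2133 ppm with APF and 1327 ± 826 ppm with mock in the run experiment, where all 8 arrays were above background, and its adjusted p over both was also 0.626. EFNA1 and JAK1 had the lowest p (adjusted p = 0.460 each) and were below the limit on all 16 arrays, as were TEK, MARK3, HNRNPD and TEC. Further probes of HNRNPD differed by -0.00207 ± 0.00608 and 0.00365 ± 0.00587 (SE). GPS1 was above it on 2 arrays and RREB1 on 2. The panel genes of lowest p were CDH1, MKI67 and CKAP4 (adjusted p = 0.678, 0.690 and 0.707). CDH1 read 350 ± 234 ppm with APF and 190 ± 116 ppm with mock in the run experiment (SD, n = 4), where 1 mock array read 18.5 ppm and the others 222 to 267 ppm.

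No list passed over both experiments (lowest adjusted p = 0.998, and 0.999 with an estimated correlation), with 0 members passing over all probes and 2 adjusted over the list alone, 1 in each of 2 lists. With all 28 arrays in a single fit 2 probes passed, TSC2 and a probe without a gene name, both higher. That fit gave the run experiment and the mean of the lines equal weight, where the main fit had 1 common APF term. The TSC2 difference was 0.100 there and 0.0839 in the main fit, so more than the precision changed. The APF difference did not differ between the 2 experiments for any probe past the threshold (0 probes, 490 at an unadjusted p under 0.05, limma). Of the 84 probes called in the cell line experiment, 50 had the same sign in the run experiment, where 0 of the 84 had an unadjusted p under 0.05. Across probes, the differences of the 2 experiments had r = 0.104 (rho = 0.0862), with a two-sided permutation p of 0.67 for r and 0.76 for rho from 100 regroupings of the arrays. Across probes, the differences of both experiments together and of IC against normal had r = 0.0392 (rho = 0.0127; permutation p = 0.77 and 0.89). These are 2 relations in 1 family, with Benjamini-Hochberg values of 0.77 for each r and 0.89 for each rho, and genes are not independent replicates.

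The comparison of IC with normal cells asked which transcripts differ between cells of people with and without the disease. Limma called 0 probes, and 72 had an unadjusted p under 0.05, here too fewer than a share of 0.05 of all probes. All 12 named genes of lowest p had adjusted p = 1.00, and 10 of them were below the background limit on all 12 arrays. Among these were SEC31A, a coat protein of transport vesicles (-0.0413 ± 0.00968, SE), and the transcription factor FOXO1 (0.0311 ± 0.00806), with APLP2, IDS, RAP2A, ADCYAP1, BLZF1, GRIA2, ARF5 and FOXD1. Further probes of GRIA2 differed by -0.00817 ± 0.0124 and -0.00253 ± 0.0117 (SE). PDYN, the prodynorphin gene, was above it on 1 of 6 normal arrays and 0 of 6 IC arrays, and LTBP4, a binding protein of latent TGF-beta, on 2 of 6 and 1 of 6. The panel genes of lowest p were MKI67, MMP9 and MAPK3, all with adjusted p = 1.00. The gelatinase MMP9 read 90.2 ± 119 ppm in IC and 101 ± 85.9 ppm in normal cells (SD, n = 6 each). MKI67 and MAPK3 were below the limit on all 12 arrays.

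No gene list passed in the IC comparison. The lowest p were those of the cell junction genes (20 measured, 13 with a positive difference) and the keratin and urothelial differentiation genes (14 measured, 10 with a positive difference), each with an adjusted p of 0.657 and of 0.957 with an estimated correlation. In each list 0 members passed over all probes and 0 adjusted over the list alone. The 12 arrays also divided by their number in the labels, with 3 IC and 3 normal arrays on each side. Among numbers 1 to 3 limma called 0 probes for IC against normal (83 at an unadjusted p under 0.05), among numbers 4 to 6 also 0 (164), and with this division as a term 0 (129). With array weights 3 probes passed: SEC31A and LTBP4 lower and MTCH2 higher in IC, the last chosen after its value was seen. In that fit 1083 probes had an unadjusted p under 0.05 (limma), against 72 without weights.

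**Figure D2:**
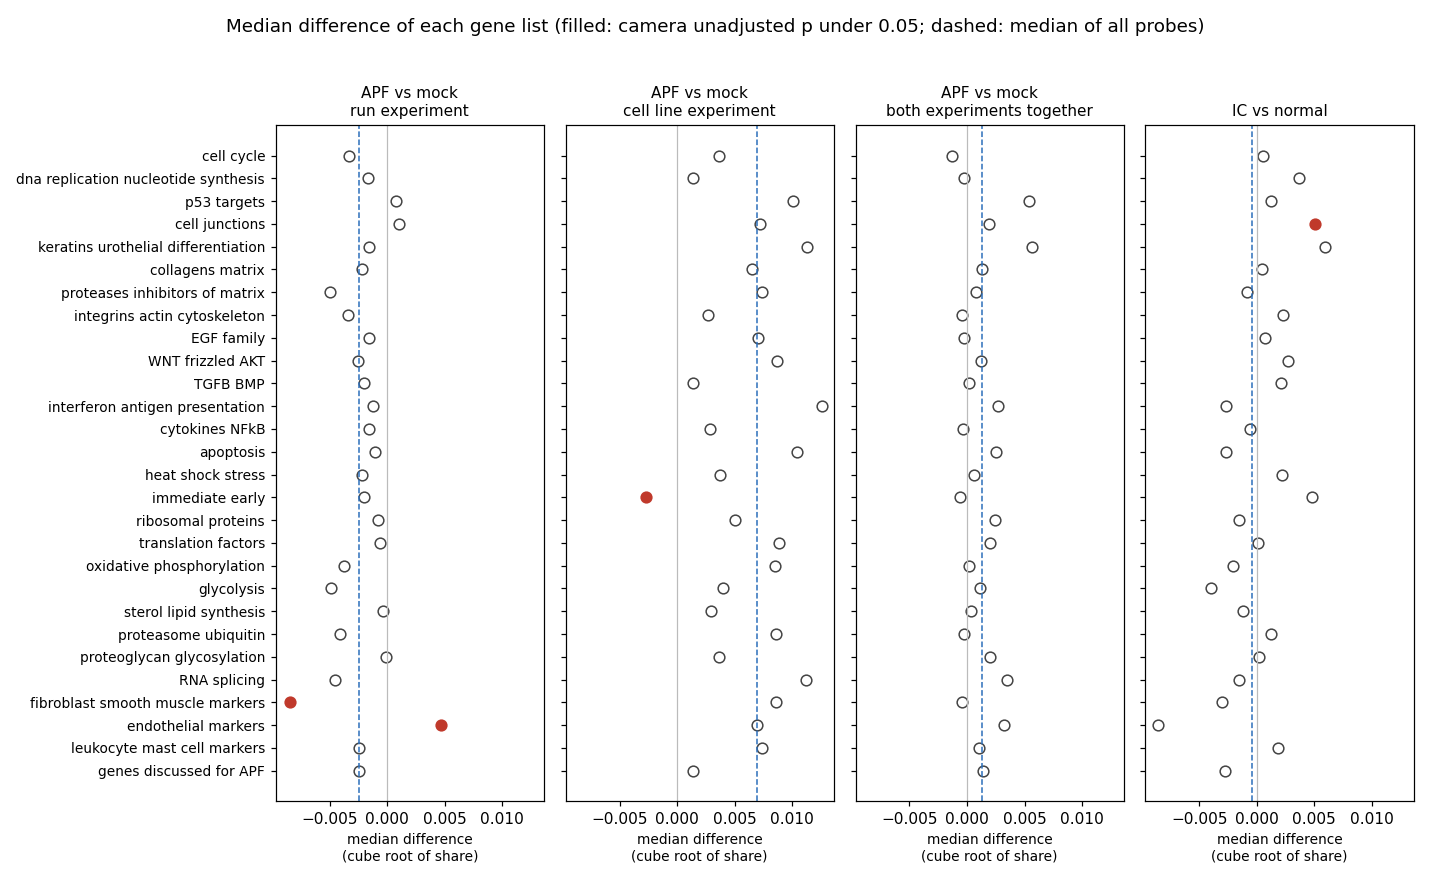
Median difference of the members of each of the 28 gene lists (y axis) on the deposited scale (x axis, cube root of the share of net signal), in 4 comparisons. Filled points have a camera p under 0.05 before adjustment and none has one after it; the dashed line is the median of all probes. In the cell line experiment that median was 0.00691, and most lists lie to the right of 0.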

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

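The tests of the membrane, of the spread of values, of a shared direction and size, and the splits within runs were chosen after the results were seen; the count of other splits was planned.

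Several genes had a single array far from the others of its group, by the gap to the nearest array over the group's range. That ratio was taken on the deposited scale, while levels beside it are in ppm. Of 102 groups tested 10 stood out, where chance gives about 5.1, and nearly all lie near background. With APF in the run experiment these were MEIS2 (ratio 0.911, 4.51 ppm against -16.5 to -10.2 ppm) and RREB1 (0.843, 88.5 ppm against -26.0 to -5.85 ppm). With mock they were LTBP4 (0.895), TEK (0.833), MARK3 (0.937) and HNRNPD (0.934), all near background, and CDH1 (0.900), at 18.5 ppm on 1 array against 222 to 267 ppm on the others. Among IC arrays they were ARF5 (0.825) and MAPK3 (0.721), and among normal arrays PDYN (0.661).

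IGDCC4 stood out because its APF difference was larger in line 2 than in line 1, by 0.199 on the deposited scale, in a test of that difference. The estimate sets line 2 (0.212) against the second line 1 pair (0.0126) and leaves out the first pair (0.149). A further IGDCC4 probe gave 0.0153 ± 0.0146 (SE) and did not pass.

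For APF against mock, the main fits called 0 probes in the run experiment, 0 in both experiments together and 84 in the cell line experiment. Several accounts of these 84 probes were weighed. The first is the membrane, since both APF arrays of line 2 were on membrane B and both mock arrays on A. Across probes, the line 2 difference had r = 0.270 with the treatment difference of line 1, which is crossed with membrane. Its r with the line 1 membrane difference was 0.0298. With 1 array of line 1 left out, the treatment r lay between 0.153 (without the second APF array) and 0.296. The membrane r minus the treatment r was -0.240 ± 0.0421 (SD over 100 resamples of probe blocks). On these arrays line 2 thus followed the treatment difference more than the membrane difference. That SD covers probes and not the spread between arrays, so whether the membrane is the cause is not decided by it. A difference in the spread of values between APF and mock arrays is argued against as the whole cause by 60 of the 84 probes being called again after quantile normalization. An effect in the run experiment of the size estimated in the cell lines is argued against: in the called direction, the 84 probes averaged 0.00242 ± 0.0127 there (SD over 33 other regroupings of the arrays) against 0.0736 in the cell lines. The latter is raised by choosing the probes on it, and 0.0250, the mean in the second line 1 pair, lies within 2 SD. Of the 84 probes, 50 had the same sign in the run experiment, and another regrouping of the 8 run experiment arrays reached 74. Whether a smaller effect is shared therefore cannot be told apart from chance here. Handling shared by the APF arrays of both lines was not tested and stays open. An atypical first APF array of line 1, the only APF array of that line in the called average, was not tested either and stays open.

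The 16 splits of the cell line arrays that the fit allows are too few for a share under 0.05, the real split being 1 of them; the real one gave 84 probes and the highest of the others 1. At an unadjusted p under 0.05 the real split gave 874 and the highest other 936, with 2 of the 16 splits, the real one included, at 874 or more. In the run experiment chance could not be excluded: 25 of 34 splits gave at least the real 83 probes at an unadjusted p under 0.05, and the highest gave 968. That split set both arrays of run 1 against both of run 4 and divided the arrays of runs 2 and 3. It also set most membrane B arrays against most membrane A arrays. Since it was picked for its count, that count is no test of a structure of these arrays other than treatment. With the run as a block, 0 probes were called for APF, with the membrane term (243 at an unadjusted p under 0.05, limma) or without it (147). Counted within runs, with the run and the membrane as terms, 3 of 7 splits gave at least the real 243, and the highest other gave 592; these splits are too few for a share under 0.05. With both experiments together 20 of 100 splits gave at least the real 292 probes (highest other 867), so chance could not be excluded there either.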

How the results depend on the processing

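The log2 scale, the background restriction and the division by number were added after the data were seen. The counts of 0 probes in the run experiment, in both experiments together and in IC against normal were also 0 under the alternatives, leaving out each array included, except for 2 probes in both together with all 28 arrays in a single fit and 3 in IC against normal with array weights. In the cell line experiment (84 probes) the count was 129 without the dimmest 0.25 of the probes, 1 with array weights, 19 with all 28 arrays, 143 without the membrane term (65 of them among the 84), 20 within line 2 and 0 within line 1 (limma, 513 at an unadjusted p under 0.05). It ranged from 1 to 1488 with 1 array left out, which leaves a lone array in a group, assumed to vary like the others: 1 without any line 2 array, and 278, 1488, 989 and 989 without the first APF, first mock, second APF and second mock array of line 1, where the line 2 arrays alone give the spread. Median centring, quantile normalization, the trended variance, the log2 scale and the background restriction gave 67 to 87 probes. On the log2 scale 81 passed, 67.9% of them higher, and 20 were among the 84. With the background restriction 67 passed, and 31 were among the 84. With median centring, quantile normalization and the trended variance 65, 60 and 66 were among them. For the difference between lines (1 probe) the count was 0 with median centring, quantile normalization, array weights, all 28 arrays or no membrane term, 46 on the log2 scale, 4 among probes above background, and 0 to 509 with 1 array left out (509 without the second mock array of line 1). Gene lists were called with fry, 1 in the run experiment and 1 in the cell line experiment, and with 1 array left out 0 to 1 in each (endothelial markers, adjusted p = 0.0430, without the third mock array of the run experiment, and ribosomal proteins, 0.0448, without the first APF array of line 1; with an estimated correlation 0.922 and 0.961). Both fold-change correlations stayed positive, from 0.0862 to 0.159 and from 0.0127 to 0.0844. The cause was not tested for the other changes. Signs turned, with none past the threshold, for TJP1 within membrane B (-0.00694), and MKI67 (0.00212) and MAPK3 (0.00679) in IC with array weights.

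Whether the replicate number pairs the arrays is undecided: the labels number runs and preparations but do not say that same-numbered arrays were handled together. Deviations from the group means of same-numbered arrays correlated at 0.681, 0.0212, 0.00739 and 0.385 in the run experiment, 0.124 in line 1, 0.0102 in line 2 and between -0.155 and 0.641 in IC and normal; 2 of 4 and 2 of 6 arrays correlated best with their own number. With the replicate number as a block, with or without membrane, 0 probes were called in every comparison. These include 0 in the cell line experiment (1480 and 707 at an unadjusted p under 0.05, limma) and 0 for the difference between lines. The block leaves fewer residual degrees of freedom in each fit, so these counts do not decide the pairing. The 2 planned log2 offsets were not run, since negative values have no log. Signal over background limits the results: at most 46.0% of an array's probes were above its limit.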

Other observations

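The comparison of the 2 lines and the tests of the division by number (splits within it included) and of probe order were chosen after the data were seen; the count of splits for IC against normal was planned.

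More probes were called between the 2 normal bladder lines (978) than with treatment (84). The treatment average takes nothing from the second line 1 pair, so these counts do not compare sizes of difference. With 1 line on each side, the p-values measure the spread between arrays. The labels number the arrays of line 1 before those of line 2, so a difference between sets of arrays cannot be told apart from line. Over both treatments and with the membrane in the fit, limma called 978 probes, 449 higher and 529 lower in line 2, and 2116 without the first APF array of line 1. Several inflammatory genes stood higher in line 2. The neutrophil chemokine CXCL1 read 5480 ± 2128 ppm in line 2 and 127 ± 60.9 ppm in line 1 (SD, n = 4 each; adjusted p = 0.00160). The monocyte chemokine CCL2 read 4073 ± 3809 and 252 ± 161 ppm, and PTGS2, the inducible cyclooxygenase, 2084 ± 1784 and 15.3 ± 24.7 ppm (adjusted p = 0.00896 and 0.00739). PTGES, which makes prostaglandin E, read 6315 ± 1204 and 1718 ± 1964 ppm (adjusted p = 0.0382). The other way, the constitutive cyclooxygenase PTGS1 read 142 ± 363 ppm in line 2 and 1153 ± 614 ppm in line 1, and the NF-kappaB subunits RELA and RELB read 103 ± 12.4 against 1116 ± 641 ppm and 83.1 ± 58.2 against 966 ± 467 ppm (adjusted p = 0.00968, 0.0246 and 0.0143). Of the 35 cytokine and NF-kappaB genes 12 were called higher and 4 lower, 16 in all adjusted over the list alone, while the list did not pass camera (adjusted p = 0.163, and 0.936 with an estimated correlation).

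The 2 APF arrays of line 1 correlated with each other at 0.649, against 0.900 to 0.914 in the other groups of the cell line experiment. Of the 8 arrays of that experiment, 1 correlated more with arrays of the other line than with those of its own. The average behind the calls for APF takes its line 1 APF values from the first APF array of line 1 alone. Whether that array is atypical was not tested. CXCL1 parted the lines on all 8, with at most 209 ppm in line 1 and at least 3443 ppm in line 2. It was picked for its difference between the lines on these same arrays, so this is no check on any array.

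The 12 arrays of the IC comparison differed by their number in the labels more than by disease. With disease in the fit, numbers 4 to 6 differed from 1 to 3 at 1017 probes, 429 higher and 588 lower. The median correlation between arrays was 0.847 within numbers 1 to 3, 0.759 within 4 to 6 and 0.621 across. Of 100 splits 1, the real one, gave as many probes, and the highest other gave 57. Since the division was chosen because the arrays were seen to part this way, that count is no test of chance. That it alone keeps probes from being called for IC is argued against by the 0 probes called for IC with the division as a term. What the numbers stand for (processing batches, sets of donors) was not tested and stays open.

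For IC against normal itself chance could not be excluded: 78 of 100 splits of the 12 arrays gave at least the real 72 probes at an unadjusted p under 0.05. The highest of the others gave 1615, as many as the division by number gives in the same fit. With that division as a term and the splits drawn within numbers 1 to 3 and 4 to 6, 52 of 100 gave at least the real 129 probes (highest other 1033), so chance could not be excluded there either.

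In the run experiment the test statistics of probes with neighbouring numbers were correlated (r = 0.172 across probes, against at most 0.0387 in 100 shuffles of their order). In IC against normal the value was 0.136, and in the cell line experiment 0.0199. A gradient over the array surface is a candidate explanation if probe numbers follow the layout, which no label states. With the running median of 51 probes taken from each array, the run experiment's value fell to 0.0900, still above the shuffles, so part of the pattern remains open. After that step 0 probes were called in the run experiment (limma, 76 at an unadjusted p under 0.05), but since it removed the pattern only in part, whether a gradient alone keeps probes from being called stays open. No biological explanation was tested.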
